A study of Caenorhabditis elegans with 8 samples.

How the data were processed

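RNA from whole adult worms of strain N2 and of a mir-83 mutant strain, at adult day 4 and day 12, was extracted with Trizol and sequenced, per the labels' protocols. The 8 libraries form 4 groups of 2. The authors deposited raw read counts per transcript in a separate sheet for each replicate number. Bowtie2, edgeR and the genome build ce11 are named by the submitters' processing notes, without versions, roles or order. How reads were trimmed, counted and assigned to isoforms is not given in the sources used here. The first sheet held 30443 lines under WormBase sequence names and the second 29023 under RefSeq accessions, so the sheets rest on different annotations. Nothing says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Depth ranged from 20.3 to 41.2 M reads per library.

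Transcripts were matched to WormBase genes of the reference annotation WBcel235, the assembly that ce11 names, and their counts were summed per gene. In the first sheet all matches were by sequence name. In the second, 24022 were by accession and 4727 by gene name only, and 70 gave different genes by accession and name. In the first sheet 217 transcripts (0.093% of reads) and in the second 274 (0.241%) matched no gene and stayed out. The 18287 genes in both sheets were kept. Genes in 1 sheet only, such as those of the mitochondrial genome, entered no test. Identical counts stood in 0.65% and 1.27% of pairs of near-equal transcripts of a gene, so reads were not simply repeated on every isoform. Reads shared by near-identical gene copies, and by overlapping or antisense genes, cannot be told apart, as the use of strand in counting is not given in the sources used here. The microRNA mir-83 itself was not analysed here, and neither were microRNA seed sites in 3' UTRs.

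Counts were normalised by TMM and filtered with filterByExpr, which left 15843 genes. TMM factors were 0.644 and 0.596 in mir-83 day 4 and between 1.08 and 1.23 in the other libraries. Tests used edgeR 4.0.16 (glmQLFit and glmQLFTest) on all 8 libraries, with 1 mean per group and a block for the replicate number, which leaves 3 residual degrees of freedom. The common biological coefficient of variation was 0.429. P-values were two-sided and Benjamini-Hochberg adjusted within each of 5 comparisons, with a threshold of 0.05. Log2 fold changes are the first-named minus the second-named group, with standard errors from the F statistic. The design, the gene lists and the rule for naming genes were fixed before the data were examined, and so was the condition that sheets with different gene lists make the replicate number a block. In the labels of replicate 1 both strains of an age share a run code, which differs between the ages, and those of replicate 2 carry none. Deviations of same-numbered libraries from their group means correlated between 0.119 and 0.415 over the 6 pairs of groups, across genes.

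Of 37 gene lists, 36 had at least 5 tested members. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, and again with a correlation estimated per list and with fry. Genes named are the 10 per direction with the smallest p among those past the threshold that have a symbol of letters and a number, the same direction in both replicates and a mean of at least 10 reads per library. Where fewer than 5 passed in a direction, the 5 with the smallest p are given as not past it. For a list, up to 4 members past the threshold with the largest change can be given, otherwise the most abundant, and all miR-83 literature genes are given at both ages. CPM values are means ± SD of 2 libraries.

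The test was run on simulated data for the day 4 comparison with 15620 genes. Changes were set only in well-counted genes, in both directions, with no other genotype effect at day 4. The spread of every gene followed the trend of the data. It recovered 16.18% of 68 genes changed 2-fold, 59.1% of 66 changed 4-fold and 72.7% of 66 changed 8-fold, with 2 false calls. The real data differ in these respects, so the rates may not carry over. Alternatives were RLE size factors, no filter, no replicate block, a replicate block within age, only the 4 libraries compared, each library left out in turn, DESeq2 1.42.0, a stricter adjusted p, a fold minimum and, chosen after seeing the data, a gene length offset and plain library sizes without TMM factors. R 4.3.3 and Python 3.11.15 were used.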

Results

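Gene expression was measured by RNA sequencing in whole Caenorhabditis elegans worms of 2 strains at 2 adult ages. N2 is the wild-type laboratory strain, and the other strain carries a mutation of mir-83, a microRNA gene. MicroRNAs are short RNAs that repress transcripts with matching sites, and the study asked what loss of this one does to gene expression and lifespan at different ages. Adults were collected at day 4 and day 12 from plates with FuDR, a drug that blocks the production of progeny. Each of the 4 groups held 2 libraries. The deposited depth was 20.3 and 32.1 M reads in N2 day 4, 34.3 and 36.9 M in N2 day 12, 21.9 and 36.2 M in mir-83 day 4, and 31.3 and 41.2 M in mir-83 day 12 (replicates 1 and 2). The 10 most abundant genes took up to 14.2% of the reads in mir-83 day 4 and at most 6.2% in the other groups. The yolk protein gene vit-5 alone took 2.43% and 3.3% of the reads in the mir-83 day 4 libraries.

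The first principal component of log2 CPM (read counts scaled to library size with TMM factors) held 58.6% of the variance and ran from mir-83 day 4 through N2 day 4 to the day 12 libraries. Across genes, which are not independent replicates, the replicates correlated at 0.975 in mir-83 day 4, 0.958 in N2 day 12, 0.949 in N2 day 4 and 0.894 in mir-83 day 12. Within the last pair, replicate 1 correlated best with N2 day 12 replicate 1, at 0.975, and replicate 2 with N2 day 4 replicate 2, at 0.952. Values for mir-83 day 12 rest on these unlike libraries.

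**Figure D1:**
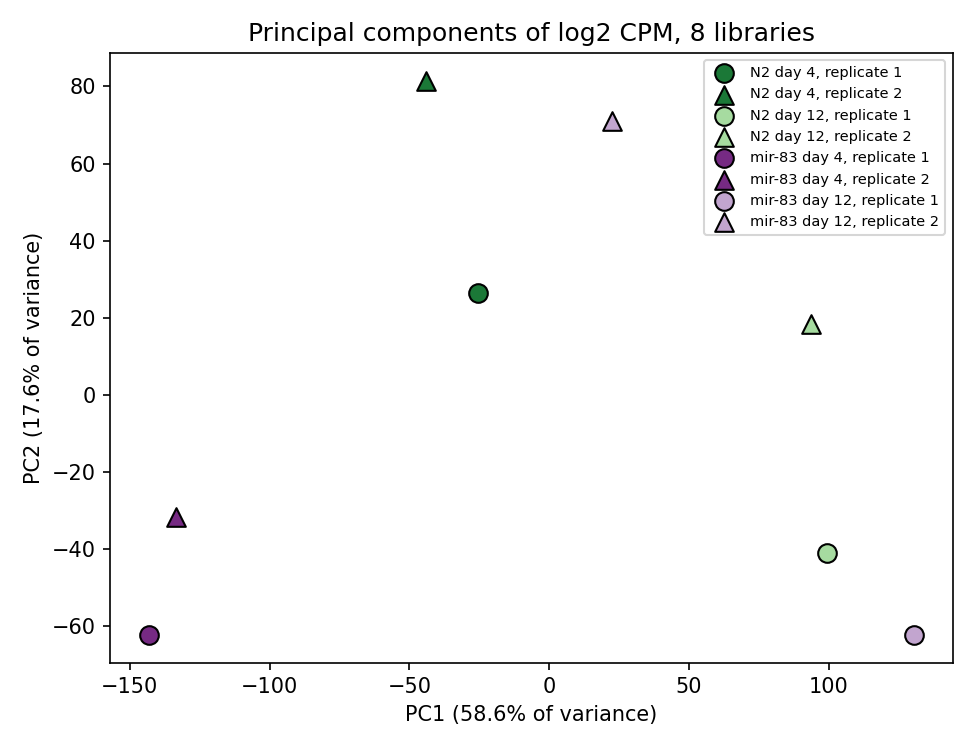
Each point is 1 library, placed by its first (x axis, 58.6% of variance) and second (y axis, 17.6% of variance) principal component of log2 CPM, with a colour for each of the 4 groups, circles for replicate 1 and triangles for replicate 2. The mir-83 day 12 replicate 2 library lies between the N2 day 4 and N2 day 12 libraries on the x axis.

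The comparison of mir-83 with N2 at day 4 asks what loss of the microRNA does to transcripts of young adults. All 6 vitellogenin genes, which encode yolk proteins made in the intestine, rose in the mutant, as did 15 of 30 muscle genes, 34 of 74 cytosolic ribosomal protein genes and 20 of 39 nuclear genes of the respiratory chain. Small heat shock genes of the hsp-16 family were far lower. The vitellogenin gene vit-2 rose by a log2 fold change of 2.58 ± 0.44 (SE, n = 2 per group, adjusted p = 0.0246), from 6883 ± 278 CPM in N2 to 42917 ± 8310 in the mutant (SD). The near-identical genes vit-3 and vit-4, which may share reads, rose by 3.41 ± 0.61 and 2.95 ± 0.52. Of 15843 genes tested, 701 were higher and 416 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, smallest adjusted p 0.0211). These levels are on the scale of the TMM factors, and with plain library sizes, chosen after seeing the data, 210 were higher and 3817 lower, and the median log2 fold change of all genes was -0.99 in place of -0.14. Adjusted over the list alone, 6 vitellogenin genes passed, and the list stood above other genes by camera (adjusted p = 9.18e-06), though not past the threshold with an estimated correlation (adjusted p = 0.586).

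Of 30 genes of body wall and pharyngeal muscle, 15 rose, 0 fell and 15 did not pass (25 passed adjusted over the list alone). The body wall myosin heavy chain gene unc-54 rose by 3.02 ± 0.59, from 155 ± 78 to 1101 ± 25.5 CPM, and the pharyngeal myosin gene myo-2 by 3.46 ± 0.74. Of 74 cytosolic ribosomal protein genes, 34 rose and 0 fell (60 passed adjusted over the list alone), including rpl-4 (2.21 ± 0.31) and rps-5 (1.97 ± 0.37). Of 39 nuclear genes of the respiratory chain, 20 rose and 0 fell (28 passed adjusted over the list alone). The ATP synthase genes atp-1 and atp-2 rose by 2.02 ± 0.29 and 1.88 ± 0.28, and sdha-1, of succinate dehydrogenase, by 2.19 ± 0.34. The medians of the muscle, ribosomal and respiratory lists were 1.85, 1.18 and 1.16. Camera called the lists at adjusted p = 4.11e-12, 5.28e-19 and 2.41e-11, and none of these 3 calls held with an estimated correlation (adjusted p = 0.586 with an estimated correlation). On plain library sizes 11 muscle genes rose and 1 fell, 8 ribosomal genes rose and 1 fell, and 9 respiratory genes rose and 1 fell, with medians of 1.0014, 0.33 and 0.30.

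Of 50 lysosomal protease and V-ATPase genes, 14 rose and 0 fell (25 passed adjusted over the list alone), among them the aspartic protease gene asp-3 (2.86 ± 0.52) and the cathepsin B gene cpr-5 (2.75 ± 0.60). Of 22 intestinal genes, 8 rose and 0 fell (8 passed adjusted over the list alone), including the intestinal actin gene act-5 (2.34 ± 0.36) and the desaturase gene fat-7 (3.58 ± 0.80). Of 50 lipase and beta-oxidation genes, 8 rose and 0 fell (11 adjusted over the list alone), including acdh-10, an acyl-CoA dehydrogenase gene on chromosome X from 17213144 to 17214903 of WBcel235 (2.05 ± 0.24). Of 33 proteasome genes, 6 rose and 0 fell (11 adjusted over the list alone), with rpn-1 at 1.67 ± 0.29. Camera called these 4 lists at adjusted p = 2.18e-09, 9.18e-06, 1.3e-05 and 2.74e-06 in this order. The adjusted p was 0.586, 0.706, 0.586 and 0.767 with an estimated correlation. With plain library sizes 6 lysosomal genes rose and 4 fell, 3 intestinal genes rose and 0 fell, 4 lipase genes rose and 2 fell, and 1 proteasome gene rose and 5 fell, and the medians of the last 2 lists were negative (-0.17 and -0.20).

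Of 26 oocyte and eggshell genes, 5 rose and 0 fell (16 adjusted over the list alone), including the eggshell proteoglycan gene cpg-2 (1.93 ± 0.36) and mex-5, a maternal regulator of embryonic polarity (1.71 ± 0.36). Of 18 embryonic genes, 3 fell and 0 rose (6 adjusted over the list alone), namely sdz-28 (-5.43 ± 0.88), sdz-4 (-4.78 ± 1.15) and sdz-1 (-4.03 ± 0.90). The list medians were 1.17 and -2.09. Camera called the oocyte list at adjusted p = 1.77e-06 and the embryonic list at adjusted p = 7.28e-05, and with an estimated correlation the adjusted p was 0.754 and 0.586. Of 28 germline and meiosis genes, 5 rose (5 adjusted over the list alone), including gld-1 (1.54 ± 0.29) and daz-1 (1.64 ± 0.29), and the list, with a median of -0.16 and a mean of 0.16, was not called (adjusted p = 0.262). Of 29 neuronal genes, 3 rose and 0 fell (5 adjusted over the list alone), among them egl-3 and egl-21, which process neuropeptides (2.49 ± 0.44 and 1.99 ± 0.27). The neuronal list was called at adjusted p = 0.00378 by camera, and at adjusted p = 0.746 it was not with an estimated correlation. The neuronal median was -0.52 in place of 0.34 with plain library sizes, 2 oocyte genes rose and 1 fell (median 0.32), 1 germline gene rose and 15 fell (median -1.01), and 7 embryonic genes fell (median -2.92). Without mir-83 day 4 replicate 2 the neuronal median was 0.71.

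The genes that fell with the smallest p included 4 of the hsp-16 family, small chaperones that are induced by heat and other stress. The gene hsp-16.41, on chromosome V from 1805178 to 1805875, fell by a log2 fold change of -6.28 ± 0.86, from 54.5 ± 31.4 CPM in N2 to 0.66 ± 0.524 in the mutant. Its neighbour hsp-16.2, from 1804334 to 1804957, fell by -5.71 ± 0.77. The annotated copies hsp-16.48 (T27E4.3) and hsp-16.48 (T27E4.9), on chromosome V at 9088131 to 9088617 and 9089280 to 9089766, fell by -4.72 ± 0.52 and -4.64 ± 0.51, and how reads divide between copies is uncertain. Of 20 heat shock genes, 6 fell, 3 rose and 11 did not pass (14 passed adjusted over the list alone), while 12 fell and 0 rose in edgeR with plain library sizes, and the list was not called (adjusted p = 0.0625). Other genes that fell were the bZIP factor gene zip-8 (-4.98 ± 0.56), the C-type lectin gene clec-266 (-4.31 ± 0.52), the cuticle collagen gene dpy-14 (-4.39 ± 0.57), the F-box gene fbxc-40 (-5.27 ± 0.69), sdz-25 (M116.4) (-6.05 ± 0.80) and the hedgehog-related gene wrt-10 (-4.25 ± 0.57), all at adjusted p = 0.0211.

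Among the genes that rose with the smallest p was the glycerol-3-phosphate dehydrogenase gene gpdh-1, on chromosome I from 14075837 to 14078211, which rose by 3.44 ± 0.34, from 11.6 ± 3.7 to 124 ± 4.08 CPM. The myo-inositol transporter gene hmit-1.1 rose by 3.11 ± 0.32, the betaine transporter gene snf-3 by 2.71 ± 0.30, the neprilysin gene nep-17 by 3.21 ± 0.38, maph-1.3 by 2.71 ± 0.31 and noa-1 by 2.70 ± 0.28. The loci C01B4.9 and Y19D10A.12 on chromosome V, which share the name mct-2 and may share reads, rose by 2.61 ± 0.24 and 2.61 ± 0.25.

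Of 8 genes that the literature connects with miR-83, 3 rose and 5 did not pass. The saposin-like gene spp-9, on chromosome X from 11487784 to 11488203, rose by 3.29 ± 0.34 (adjusted p = 0.0211), the collagen gene col-178 by 3.25 ± 0.72 (adjusted p = 0.0384) and daf-16, the FOXO factor of insulin signalling, by 1.44 ± 0.22 (adjusted p = 0.0219). The log2 fold change was 0.83 ± 0.24 for cdc-42, 1.39 ± 0.60 for peb-1, 0.69 ± 0.61 for din-1, 0.41 ± 0.27 for cup-5 and 0.00 ± 0.32 for pat-3. Adjusted over the list alone 4 passed, which is not independent evidence, since members may have been picked on these samples. Camera called the list at adjusted p = 0.00161, and with an estimated correlation the adjusted p was 0.586. Of 20 genes induced by DAF-16, 4 rose and 0 fell (5 adjusted over the list alone), including icl-1 of the glyoxylate cycle (3.61 ± 0.47) and the catalase gene ctl-1 (1.87 ± 0.27). That list was called at adjusted p = 0.000328, and with an estimated correlation the adjusted p was 0.754. Without N2 day 4 replicate 2 it was not called, and its median of 1.07 became 0.46, while it was 1.96 without N2 day 4 replicate 1 and 0.66 without mir-83 day 4 replicate 1. Among 29 longevity regulators hlh-30 and aak-2 also rose (2.16 ± 0.50 and 1.52 ± 0.31) and sir-2.1 fell (-1.53 ± 0.25), with 5 members past the threshold adjusted over the list alone, and the list was not called (adjusted p = 0.262). With plain library sizes 2 of the 8 literature genes rose, daf-16 not among them, and 0 longevity regulators rose and 10 fell in edgeR. Of the 20 genes induced by DAF-16, 3 rose and 0 fell with that scaling, and the list median was 0.20. Of 11 genes repressed by DAF-16, vit-2 and vit-5 among them, 2 rose and 1 fell with TMM factors (median -0.49). Camera did not call that list. With plain library sizes 2 of them rose and 3 fell (median -1.37).

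Without the replicate block 321 genes passed at day 4 (204 higher, 117 lower), and 0 passed at an adjusted p under 0.01 in edgeR, where 4179 had an unadjusted p under 0.05 and DESeq2 called 2625 at 0.05. With either mir-83 day 4 library left out 0 genes passed, with N2 day 4 replicate 1 or 2 left out 56 or 11 passed, and with mir-83 day 12 replicate 1 or 2 left out 2504 or 2435 passed. The spread per gene was estimated over all 8 libraries, so the day 12 libraries also bear on which genes pass at day 4. The 701 and 416 genes kept their direction with plain library sizes, and 209 and 416 of them still passed. That scaling lowers all genes of mir-83 day 4 together, so the direction of the 416 was bound to hold. Camera still called the 19 lists in the same direction, but it compares a list with other genes and hardly responds to such a shift. None of the 19 was called with an estimated correlation (adjusted p from 0.586 to 0.8 with an estimated correlation). Without N2 day 4 replicate 2 camera lost the calls of DAF-16 induced genes, collagens, saposin-like, antimicrobial, fatty acid and glutathione S-transferase genes, with medians of 0.46, 0.22, 0.17, 0.34, 0.09 and 0.19. Without mir-83 day 4 replicate 1 it lost those of collagens, saposin-like, antimicrobial and glutathione S-transferase genes, with medians of 0.17, 0.22, -0.10 and 0.38.

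**Figure D2:**
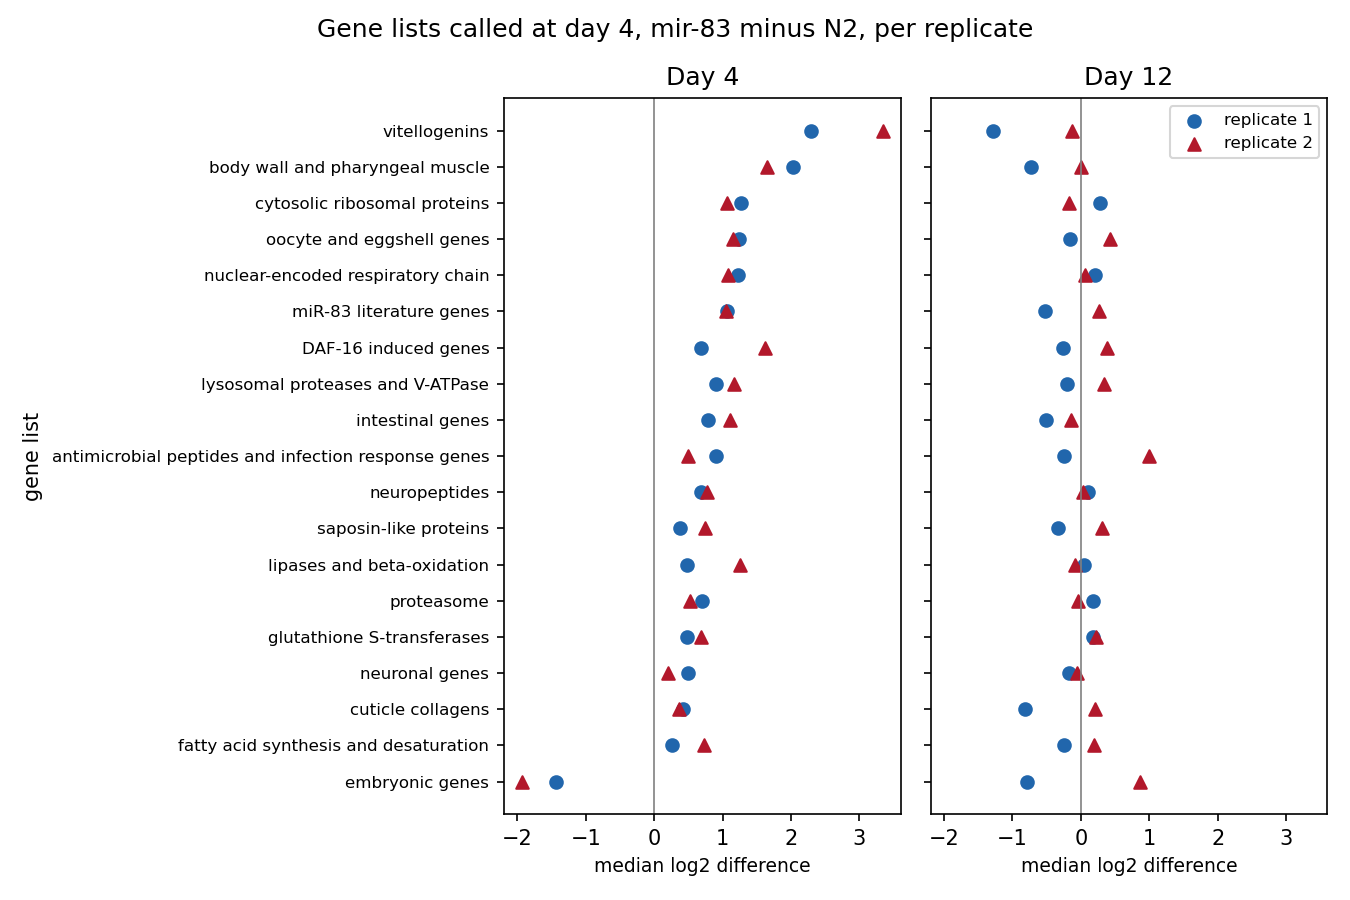
Each line of the plot is a gene list called at day 4, and each point is the median log2 difference of its members, mir-83 minus N2 (x axis), within replicate 1 (circles) or replicate 2 (triangles), at day 4 on the left and day 12 on the right. Vitellogenin medians were 2.30 and 3.34 at day 4 and -1.29 and -0.13 at day 12.

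At day 12, the comparison asks whether the strains differ in old adults. No gene separated them past the threshold in edgeR, where 306 genes had an unadjusted p under 0.05 and chance gives 792, and DESeq2 called 4. Those 4, chosen after their values were seen, were scb-1 and nep-22, higher in mir-83, and C17D12.3 (Y47H9A.1) and Y110A2AL.9, lower. The transcript of scb-1 stood at 28.4 ± 2.71 CPM in mir-83 and 4.6 ± 0.0623 in N2 (SD, n = 2), a log2 fold change of 2.61 ± 0.46 (SE, edgeR adjusted p = 0.9997, DESeq2 adjusted p = 3.73e-06). The neprilysin gene nep-22 stood at 3.99 ± 2.82 against 0.332 ± 0.0337 CPM (edgeR adjusted p = 0.9997, DESeq2 adjusted p = 2.26e-06). The other genes with the smallest p were exc-13 (2.07 ± 0.65), clec-3 (2.79 ± 0.96) and col-62 (1.66 ± 0.59) on the higher side. On the lower side they were fip-2 (-1.91 ± 0.37), the polarity gene spat-2 (-1.30 ± 0.29), the germ granule helicase gene glh-1 (-1.01 ± 0.24), the RNA polymerase I gene rpoa-1 (-1.22 ± 0.30) and set-9 (-1.64 ± 0.40). The genotype effect had the same sign in both replicates for 41.9% of genes, against 78.5% at day 4. The test was not simulated for day 12, so the lack of calls in edgeR does not show that the strains are alike.

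None of the 8 miR-83 literature genes passed at day 12, over all genes or adjusted over the list alone (0 of 8). The log2 fold change was -0.97 ± 0.32 for spp-9, -0.41 ± 0.22 for daf-16, -0.25 ± 0.69 for col-178, -0.64 ± 0.62 for din-1, -0.57 ± 0.59 for peb-1, 0.16 ± 0.27 for cup-5, 0.09 ± 0.24 for cdc-42 and 0.01 ± 0.32 for pat-3. Camera called 12 of 36 lists, 4 up and 8 down, and 0 with an estimated correlation (adjusted p = 0.937 with an estimated correlation). With the gene length offset, chosen after seeing the data, it called 4, of which 0 were up. Of 90 sperm genes, many of them near-identical major sperm protein genes, 0 passed, and the list had the smallest adjusted p (8.05e-09, down). Its median was 1.25 in replicate 1 and -3.49 in replicate 2, and over both it was -1.14, which became 0.32 without mir-83 day 12 replicate 2, 0.65 without N2 day 12 replicate 2, -3.06 without mir-83 day 12 replicate 1 and -2.66 without N2 day 12 replicate 1. Germline and meiosis genes had medians of -0.24 and -0.50 in the replicates, and -0.0590 without mir-83 day 12 replicate 2, where camera turned to the other direction. Their median of -0.35 over both became -0.60 without mir-83 day 12 replicate 1, and -0.16 without N2 day 12 replicate 1, where the list was not called. Across genes, the day 12 effects of the replicates correlated at -0.412, against 0.666 at day 4. Without mir-83 day 12 replicate 2 camera called 20 lists, and edgeR still called 0 genes with any of the 8 libraries left out.

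The difference between the genotype effects at day 12 and day 4 asks whether the effect of the mutation depends on age. No gene passed in edgeR (smallest adjusted p 0.0549, 2911 genes at an unadjusted p under 0.05), and DESeq2 called 1309. The genes with the smallest p were mostly those with large values at day 4. For hsp-16.48 (T27E4.9) and hsp-16.48 (T27E4.3) the differences were 4.69 ± 0.65 and 4.75 ± 0.67, for clec-266 4.57 ± 0.68, for zip-8 4.71 ± 0.70 and for sdz-25 (M116.4) 6.56 ± 0.98. For spp-9 the difference was -4.25 ± 0.46, for nep-17 -4.16 ± 0.51, for maph-1.2, which may share reads with maph-1.3, -3.51 ± 0.44, and for the mct-2 loci -3.14 ± 0.33 and -3.12 ± 0.35. Among the miR-83 literature genes the difference was also -1.86 ± 0.31 for daf-16 and -3.50 ± 0.99 for col-178, and 3 of 8 passed adjusted over the list alone. Those 3 are not independent evidence, since members may have been picked on these samples.

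Camera called 18 lists for this difference, 2 up and 16 down, and 0 with an estimated correlation (adjusted p from 0.736 to 0.879 with an estimated correlation). Vitellogenins had a median difference of -3.56 (6 of 6 genes adjusted over the list alone), muscle genes of -2.07 (22 of 30) and ribosomal protein genes of -1.08 (35 of 74), while embryonic genes had one of 2.17 (3 of 18). The genotype effects at the ages, which share no library, correlated at 0.0238 across genes. The count of 0 genes became 535 without mir-83 day 12 replicate 2, 551 without its replicate 1, 36 without N2 day 4 replicate 1 and 2 without N2 day 12 replicate 1. It became 34 with RLE size factors, 314 without the filter on low counts and 1744 (1636 higher, 108 lower) with plain library sizes, where the medians of vitellogenin, muscle, ribosomal and embryonic genes were -2.67, -1.21, -0.22 and 3.05.

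**Figure D3:**
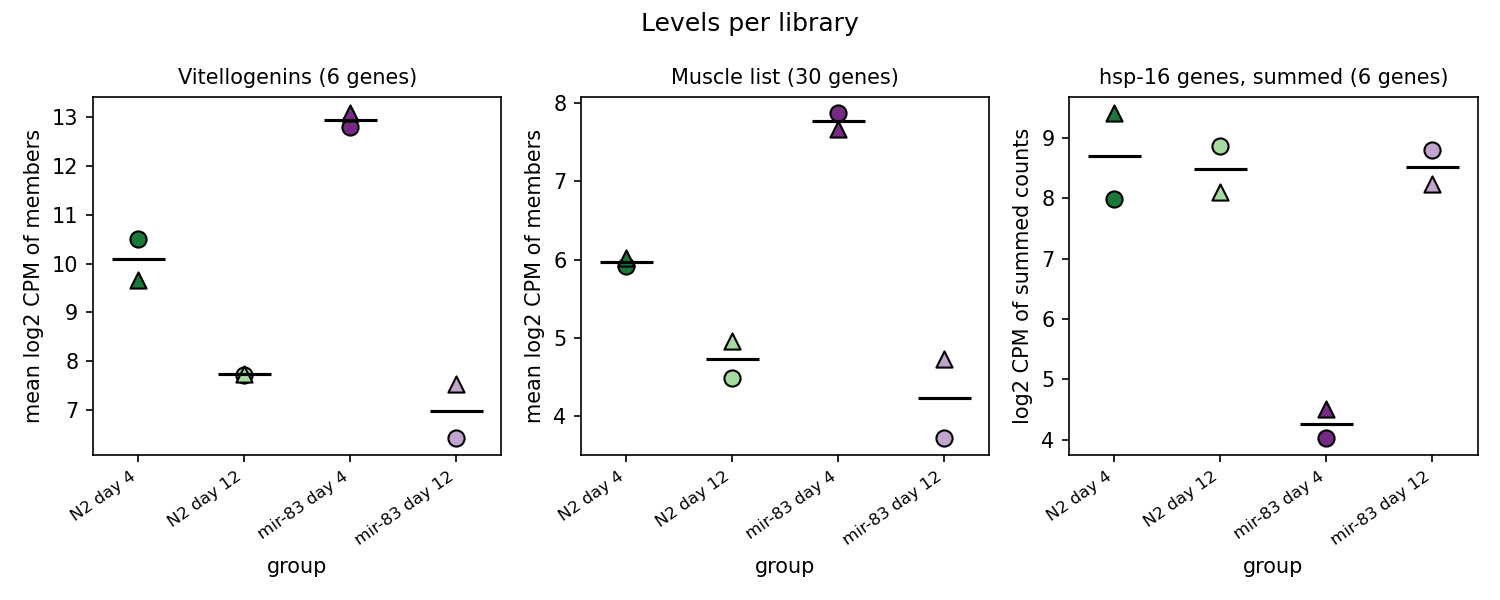
Each point is 1 library (circles replicate 1, triangles replicate 2), lines are means of 2 libraries, and the y axes give the mean log2 CPM of 6 vitellogenin genes, of 30 muscle genes, and the log2 CPM of the summed counts of 6 hsp-16 genes. The mir-83 day 4 libraries stand at 4.03 and 4.51 for hsp-16, and the other 6 libraries between 7.98 and 9.41.

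In N2, day 12 was compared with day 4 to describe ageing in the wild type. Of 146 cuticle collagen genes 30 fell with age, as did all 6 vitellogenin genes, 13 of 50 lysosomal genes and 25 of 136 C-type lectin genes, while 7 of 28 germline genes and 3 of 14 microRNA pathway genes rose. The collagen genes col-92, col-93 and col-94, neighbours on chromosome III between 10982139 and 10987873 that may share reads, fell by -6.45 ± 0.62, -7.76 ± 0.59 and -6.35 ± 0.70 (SE, n = 2 per group). The yolk gene vit-5 went from 8292 ± 306 to 1478 ± 230 CPM. In all, 334 genes were higher and 380 lower at day 12 (edgeR, Benjamini-Hochberg, smallest adjusted p 0.0143), and 657 and 290 with plain library sizes, where 5 vitellogenin genes fell.

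No collagen, vitellogenin or lysosomal gene rose, and adjusted over the list alone 57, 6 and 37 of them passed, including the aspartic protease gene asp-2 (-3.28 ± 0.43). Among genes of innate immunity, 5 of 13 lysozyme genes fell (8 adjusted over the list alone), including lys-1 (-2.63 ± 0.41) and lys-8 (-2.81 ± 0.47). Of 24 saposin-like genes 7 fell (17 adjusted over the list alone), including spp-3 (-3.79 ± 0.43), and of 136 C-type lectin genes 25 fell (58 adjusted over the list alone). Of 30 muscle genes 9 fell and 0 rose (13 adjusted over the list alone), including the myosin light chain gene mlc-3 (-3.17 ± 0.34). Other genes that fell were nspc-19 (-3.13 ± 0.34), nspc-16 (-3.58 ± 0.41), the acid phosphatase gene acp-6 (-3.81 ± 0.42) and the calponin-like gene clik-1 (-3.15 ± 0.35). These 7 lists were called down by camera, the largest adjusted p being 0.00105 for lysozymes, and each had an adjusted p of 0.662 with an estimated correlation.

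Of 28 germline and meiosis genes 7 rose with age in N2 and 0 fell (20 adjusted over the list alone, and 14 over all genes with plain library sizes), including the helicase genes glh-1 (1.60 ± 0.25) and glh-2 (1.93 ± 0.32). Of 14 microRNA pathway genes 3 rose and 0 fell (6 adjusted over the list alone), namely lin-41, a target of the let-7 microRNA (1.81 ± 0.29), the Dicer gene dcr-1 (1.72 ± 0.28) and the Drosha gene drsh-1 (1.33 ± 0.24). Both lists were called up (adjusted p = 1.13e-09 and 0.000254), and with an estimated correlation the adjusted p was 0.662 for both. Of 90 sperm genes 0 passed, over all genes or adjusted over the list alone, and 88 had positive values, with medians of 0.61 and 3.86 in the replicates. That list too was called up (adjusted p = 1.23e-11), and with an estimated correlation its adjusted p was 0.662. Its median of 2.59 became 0.57 without N2 day 12 replicate 2 and 3.92 without its replicate 1. Of 29 longevity regulators 4 rose and 1 fell (8 and 0 with plain library sizes). The insulin receptor gene daf-2 rose by 1.59 ± 0.36 and let-363, which encodes TOR, by 1.54 ± 0.24. Genes with the smallest p among those that rose were attf-6 (2.20 ± 0.27), pad-1 (2.08 ± 0.26), set-2 (1.81 ± 0.24), smc-4 (1.75 ± 0.24), zyg-8 (2.12 ± 0.29), npp-21 (1.87 ± 0.25), mask-1 (2.03 ± 0.28), smg-2 (2.14 ± 0.30), gcn-1 (1.80 ± 0.25) and lpd-3 (1.74 ± 0.24). The median exonic length was 3997 bases among genes that rose and 972 among genes that fell, against 1309 for all tested genes. With the trend of each library on gene length removed, an alternative chosen after seeing the data, 16 genes were higher and 259 lower, 9 of those 10 genes no longer passed, and neither did the microRNA pathway list.

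Camera called 22 of 36 lists for age in N2, 5 up and 17 down, and 0 with an estimated correlation (adjusted p from 0.662 to 0.77 with an estimated correlation). Without the replicate block 136 genes passed (48 higher, 88 lower), zyg-8 not among them. The number of genes that passed was 0 without either N2 day 12 library, in edgeR, where all 8 libraries gave 4459 genes at an unadjusted p under 0.05 and 3257 by DESeq2. It was 3 and 471 without N2 day 4 replicates 1 and 2, 130 and 128 without mir-83 day 4 replicates 1 and 2, and 2472 and 2424 without mir-83 day 12 replicates 1 and 2. In the labels of replicate 1 each age carries a run code of its own, so age and run cannot be told apart there.

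In mir-83, the same comparison of ages gave 28 of 30 muscle, 64 of 74 ribosomal protein, 40 of 50 lysosomal and 19 of 22 intestinal genes that fell, and hsp-16 genes that rose. The tropomyosin gene lev-11 fell by -3.94 ± 0.30, from 1305 ± 218 to 85.1 ± 17.7 CPM, and the aspartic protease gene asp-1 by -6.12 ± 0.44, from 6046 ± 625 to 89.4 ± 44.9 CPM (n = 2 per group). In all, 2022 genes were higher and 2402 lower at day 12 (edgeR, smallest adjusted p 0.00145), and 5915 and 976 with plain library sizes, where the median of all genes was 1.01 in place of 0.05. All 6 vitellogenin genes fell (median -5.78, 6 adjusted over the list alone), as did 28 of 30 muscle genes (median -3.64, 30 adjusted over the list alone) and 40 of 50 lysosomal genes (median -2.53, 43 adjusted over the list alone). Of 74 ribosomal protein genes 64 fell and 1 rose (median -1.49, 69 adjusted over the list alone), of 39 respiratory chain genes 27 fell (median -1.19, 32 adjusted over the list alone), and of 22 intestinal genes 19 fell (median -2.71, 20 adjusted over the list alone). Camera called these 6 lists, the largest adjusted p being 4.67e-06 for vitellogenins, and each had an adjusted p of 0.51 with an estimated correlation. On plain library sizes 6 vitellogenin, 23 muscle, 27 lysosomal, 26 ribosomal, 11 respiratory and 11 intestinal genes fell, and 0, 1, 4, 2, 4 and 1 rose in edgeR. The medians of these lists were then, in the same order, -4.81, -2.68, -1.57, -0.53, -0.22 and -1.74. The genes gpdh-1 (-5.93 ± 0.39), hmit-1.1 (-5.39 ± 0.36), nep-17 (-5.23 ± 0.41), mlc-3 (-5.04 ± 0.38), clik-1 (-5.11 ± 0.39) and nspc-19 (-4.84 ± 0.37) fell too. The collagen gene col-93 went from 231 ± 38.6 to 0.0606 ± 0.0857 CPM, with 0 reads in 1 of the day 12 libraries.

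Genes that rose with age in mir-83 included hsp-16.48 (T27E4.9) and hsp-16.48 (T27E4.3) (4.32 ± 0.50 and 4.39 ± 0.52), hsp-16.41 (6.15 ± 0.86), zip-8 (5.45 ± 0.57), clec-266 (5.40 ± 0.55) and fbxc-40 (6.09 ± 0.70). The DNA repair genes rad-50 (2.46 ± 0.26) and fnci-1 (2.39 ± 0.27), the Polycomb-group gene mes-3 (2.29 ± 0.24), the RNA-dependent RNA polymerase gene rrf-2 (3.52 ± 0.40) and evl-14 (2.16 ± 0.26) rose as well. Of 18 embryonic genes 7 rose and 0 fell (7 adjusted over the list alone), and that list was called up at adjusted p = 0.0118, with an adjusted p of 0.602 with an estimated correlation. Without mir-83 day 12 replicate 2 it was not called (adjusted p = 0.0942 by camera), and its median of 1.65 became 1.38, nor was it with plain library sizes (adjusted p = 0.0724, median 2.62). Camera called 28 of 36 lists, 4 up and 24 down, and 0 with an estimated correlation (adjusted p from 0.51 to 0.709 with an estimated correlation). Of the genes called lower with age, 344 were called in both N2 and mir-83 where independent lists would share 57.6, and of those called higher 153 were, where independent lists would share 42.6. Both strains use 1 estimate of the spread per gene, so genes that pass easily do so in both, and 57.6 and 42.6 may be too low. Another 21 genes called higher in N2 were called lower in mir-83, and 0 the other way round in edgeR. These overlaps and opposite calls were counted with TMM factors only. With plain library sizes, 2294 of the 2402 genes called lower with age in mir-83 kept their direction and 976 still passed. All 2022 called higher still passed with that scaling. Age effects in the strains correlated at 0.624 across genes, at 0.651 within replicate 1, where the strains share a run code at each age, and at 0.345 within replicate 2. Across replicates they correlated at 0.407 (N2 of replicate 1) and 0.656 (N2 of replicate 2). The count of 4424 fell to 579 or 870 without mir-83 day 4 replicate 1 or 2, and to 2609 without mir-83 day 12 replicate 1. With RLE size factors the median log2 fold change of all genes was 0.18 in place of 0.05.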

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

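Of the tests below, those for an exchange with N2 day 4 replicate 2, for a wrong label, for gene length, for the shift from abundant genes and for fewer germ cells were chosen only after the result was seen, as were the second choice of markers and the fit with plain library sizes. Groups of 2 libraries are too small to test whether a single sample stands apart.

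The genotype effect of 18 gene lists differed between day 12 and day 4 by camera on the interaction term, and for each the adjusted p with an estimated correlation was between 0.736 and 0.879. The median difference (log2, day 12 minus day 4) was -3.56 for vitellogenins, -2.07 for body wall and pharyngeal muscle, -1.59 for miR-83 literature genes, -1.34 for microRNA pathway genes, -1.10 for the nuclear-encoded respiratory chain, -1.08 for cytosolic ribosomal proteins and -1.0006 for oocyte and eggshell genes. It was -0.95 for intestinal genes, -0.87 for cuticle collagens, -0.85 for lysosomal proteases and V-ATPase, -0.81 for DAF-16 induced genes, -0.73 for lipases and beta-oxidation, -0.62 for neuropeptides, -0.49 for the proteasome, -0.35 for neuronal genes and -0.26 for germline and meiosis genes. It was 2.17 for embryonic genes and 0.62 for histones. With 1 library left out, some calls ended and other medians moved by over 1.5 times, and medians without it are in parentheses. Without N2 day 4 replicate 1 the calls of germline genes (-0.03) and the proteasome (-0.25) ended, and the medians of DAF-16 induced genes (-1.89), neuropeptides (-1.08), intestinal genes (-1.84), lipases (-1.61) and histones (0.96) moved. Without N2 day 4 replicate 2 the call of DAF-16 induced genes ended (-0.34), histones turned by camera's direction (0.23), and germline genes (-0.53) and neuropeptides (-0.28) moved. Without N2 day 12 replicate 1 the calls of collagens (-0.51), oocyte (-0.47), germline (-0.13) and microRNA pathway genes (-0.71) ended, and neuronal genes (-0.63) moved. Without N2 day 12 replicate 2 that of histones (0.74) ended, and neuropeptides (-0.19) moved. Without mir-83 day 4 replicate 1 germline genes (-0.50), neuronal genes (-0.09), neuropeptides (-0.30) and histones (1.27) moved. Without mir-83 day 4 replicate 2 the call of germline genes (-0.08) ended, histones turned by camera's direction (0.11), and neuronal genes (-0.62), the proteasome (-0.26) and lipases (-0.35) moved. Without mir-83 day 12 replicate 1 the calls of DAF-16 induced genes (-0.35), collagens (-0.67), neuropeptides (-0.29), the microRNA pathway (-0.45) and histones (0.73) ended, and lysosomal genes (-0.55), germline genes (-0.59) and the proteasome (-0.80) moved. Without mir-83 day 12 replicate 2 the calls of germline genes (-0.05), the proteasome (-0.23) and histones (0.48) ended. DAF-16 induced genes (-1.98), lysosomal genes (-1.36), collagens (-1.60), neuronal genes (-0.79), neuropeptides (-1.13), intestinal genes (-1.87), lipases (-1.27) and the microRNA pathway (-2.22) moved. With plain library sizes the calls of germline genes (0.61), the proteasome (0.38) and histones (1.47) ended, and of lists that stayed called as lower than other genes the medians were positive for neuronal genes (0.50), neuropeptides (0.25), lipases (0.15), DAF-16 induced genes (0.08), lysosomal genes (0.03) and collagens (0.0073). Medians stayed negative but became smaller in size for vitellogenins (-2.67), muscle (-1.2), miR-83 literature (-0.72), microRNA pathway (-0.44), respiratory (-0.23), ribosomal (-0.22), oocyte (-0.12) and intestinal genes (-0.08). That of embryonic genes became larger (3.05).

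At day 4, camera called 19 lists, 18 of them higher in mir-83, but 0 with an estimated correlation, 6 fewer of them without N2 day 4 replicate 2 and 4 fewer without mir-83 day 4 replicate 1, and with the trend of each library on gene length removed, 19 of the 19 were still called in the same direction, which argues against length as the whole cause. Reads taken by a few genes are argued against as what raised the ribosomal, respiratory and muscle lists, as the values below go in opposite directions. The 10 most abundant genes of every library number 27 in all. Their reads lower all other genes in mir-83 by a log2 shift of -0.127 and -0.148 in the replicates. That shift came from shares of raw reads. The lower quartiles of the remaining ribosomal, respiratory and muscle genes (lowest 0.52) were scaled with TMM factors, so the values are not on the same scale. With plain library sizes and all members, the list medians in this order were 0.33, 0.30 and 1.0014. These medians, on the scale of raw reads, were positive, while the shift was negative in both replicates. Without these abundant genes 17 lists were still called, though camera compares a list with other genes and does not respond to such a shift. Fewer germ cells and embryos would lower oocyte, germline and embryonic genes alike, but oocyte and eggshell genes stood above all genes by at least 1.21 (log2) in both replicates, while embryonic genes had a median of -2.09. Germline and meiosis genes stood above all genes by only 0.13 and 0.04 in the replicates. With plain library sizes their median was -1.01 and that of oocyte genes 0.32, so only the oocyte list goes against fewer germ cells. An effect of genotype, fewer embryos alone, and a difference in culture between the strains stay open, untested. Fewer germ cells stay open as well, as do reads taken by a few genes for lists other than the ribosomal, respiratory and muscle ones. So does the level of the genes of the called lists as such, since with plain library sizes the median of all genes was -0.99.

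The library labelled mir-83 day 12 replicate 2 resembled N2 day 4 replicate 2 more than its group mate. An exchange of these libraries is argued against, since N2 day 4 replicate 2 correlated less with mir-83 day 12 replicate 1 than with N2 day 4 replicate 1 (difference -0.106). An exchange with N2 day 12 replicate 2, or a wrong label or mixture in this library alone, cannot be told apart from a correct label: on 99 genes that parted the strains in the other 6 libraries the median score (0 for mir-83, 1 for N2) was 1.18 for this library and 0.797 for N2 day 12 replicate 2 (1.19 and 0.805 on the 96 lower in mir-83, 0.105 and 0.676 on the 3 higher in it, scb-1 among them), but 3 of the 10 splits of those libraries, the real one included, gave as many genes (highest other 884), so the score does not identify a strain. A second choice of markers, stable with age, put this library nearer N2 for 10 of 11 genes but was as unspecific (6 of 10 splits, highest other 94), while scb-1 and nep-22, picked after their values were seen, stood at 26.5 and 5.98 CPM here against 4.56 and 0.356 in N2 day 12 replicate 2. Slower ageing in the mutant also stays open, with age scores (0 and 1 for the N2 libraries of replicate 1 at day 4 and day 12) of 0.594 here and 0.997 in mir-83 replicate 1, but N2 replicate 2 itself scored 0.189 at day 4 and 0.725 at day 12.

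The hsp-16 genes were lower in mir-83 at day 4. Reads divided between copies are argued against as the cause, because the summed count of all 6 hsp-16 genes was lower by a log2 difference of -3.95 and -4.90 in the replicates. Stress of the N2 day 4 animals alone cannot be told apart from a genotype effect, since the summed level of N2 day 4 minus N2 day 12 was -0.89 in replicate 1 and 1.30 in replicate 2. In log2 CPM the sums of replicates 1 and 2 were 7.98 and 9.41 in N2 day 4 and 8.87 and 8.11 in N2 day 12. They were 8.80 and 8.24 in mir-83 day 12, and 4.03 and 4.51 in mir-83 day 4. A genotype effect stays open.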

How the results depend on the processing

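The gene length offset and plain library sizes (no TMM factors) were chosen after seeing the data. No named gene turned its direction under any alternative run (1020 results kept direction and call, 134 lost the call, 75 gained one). Genes were named only with the same direction in both replicates, which left little room for a turn, so this does not measure stability. Of results for lists 1307 kept direction and call, 294 lost the call and 14 turned. Genes called at day 4 numbered 321 with no replicate block, 2007 with a replicate block within age, 4876 with only the 4 libraries compared, 2625 by DESeq2, 0 at an adjusted p under 0.01 in edgeR (4179 unadjusted under 0.05) and 0 to 2504 with 1 library left out. At day 12 DESeq2 called 4 genes, and edgeR 0 with any 1 library left out (306 unadjusted under 0.05 with all). For the difference between ages the counts were 34 with RLE size factors, 314 with no filter, 21 with the length offset, 1309 by DESeq2 and 0 to 551 with 1 library left out. For age in N2 they were 1075 with no filter, 136 with no replicate block, 275 with the length offset, 1450 with only the 4 libraries, 3257 by DESeq2, 0 at an adjusted p under 0.01 in edgeR (4459 unadjusted under 0.05) and 0 to 2472 with 1 library left out. For age in mir-83 they were 1300 at an adjusted p under 0.01 and 579 to 5650 with 1 library left out. Omitting the replicate block moved no other count by over 1.5 times; it ended the calls of zyg-8 for age in N2, of collagens at day 4 and of miR-83 literature and basement membrane genes for age in mir-83, and of the genes and lists recomputed no other call. Examples given as members of lists were not followed singly. With the length offset the median of all genes moved from -0.14 to -0.00557 at day 4, from -0.03 to 0.08 at day 12 and from -0.09 to 0.05 for age in N2. With plain library sizes 4027 genes were called at day 4 (210 higher), 1744 for the difference (1636 higher) and 6891 for age in mir-83 (5915 higher), the median of all genes was -0.99, 0.95 and 1.01, and proteasome genes for age in mir-83 turned (0.52). Lists called with an estimated correlation numbered 0 in each of the 5 comparisons, and with fry 0 at day 4, day 12 and for the difference, 1 for age in N2 and 15 for age in mir-83. The length offset left 4 lists at day 12. With 1 library left out, lists called ranged from 14 to 25 at day 4, 8 to 20 at day 12, 14 to 24 for the difference, 19 to 25 for age in N2 and 21 to 28 for age in mir-83. The correlation of genotype effects was -0.0782 with only the 4 libraries and -0.0863 to 0.139 with 1 library left out. With 1 library left out, lists that turned ranged, in medians at day 12, from -1.07 to 0.22 (collagens), -0.79 to 1.43 (antimicrobial), -0.60 to -0.0590 (germline), -3.06 to 0.65 (sperm), -0.94 to 0.0991 (muscle), -0.85 to 0.0907 (intestine), -0.115 to 0.218 (respiratory chain) and -1.09 to -0.105 (microRNA pathway), and for the difference from 0.11 to 1.27 (histones). For age in N2, cell cycle genes ranged from -0.0422 to 0.618, and ribosomal proteins had 0.0698 with the length offset. Germline, microRNA pathway, respiratory chain and histone lists turned by camera's direction where their median kept its sign. Individual medians of turned lists were 0.32 for sperm, -0.79 for antimicrobial and -0.0590 for germline genes without mir-83 day 12 replicate 2, 0.055 for the respiratory chain without N2 day 12 replicate 2, -0.165 for the microRNA pathway without N2 day 12 replicate 1, and 0.235 and 0.11 for histones without N2 day 4 replicate 2 and mir-83 day 4 replicate 2. Where a library was left out, the lone sample of its group is assumed to vary like the other groups. Apart from fewer libraries and the settings' own construction, the cause was not tested. The block within age was not run for the comparisons of ages, and the 4-library fit not for the difference. Seed-site alternatives were not run, and the pseudocount alternative has no use with counts. At this depth and n, 16.18% of simulated 2-fold changes at day 4, set in well-counted genes with no other genotype effect, were recovered.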

Other observations

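The test of the mutant against the N2 age effect was chosen only after the result was seen. Camera called neuropeptides and 3 groups of detoxification genes down with age in both strains, and single members fell. Of 122 neuropeptide genes, 6 fell in N2 (14 adjusted over the list alone), and 57 fell and 3 rose in mir-83 (75 adjusted over the list alone), with an adjusted p of 0.662 and 0.522 with an estimated correlation. Of 44 glutathione S-transferase genes, 3 fell in N2 (9 adjusted over the list alone) and 18 in mir-83 (19 adjusted over the list alone), with an adjusted p of 0.662 and 0.51 with an estimated correlation. Among them gst-10 fell by -3.15 ± 0.40 in N2 and by -4.53 ± 0.42 in mir-83 (SE, n = 2 per group, edgeR adjusted p = 0.0225 and 0.00148). Of 65 UDP-glycosyltransferase genes, 4 fell in N2 (5 adjusted over the list alone) and 19 in mir-83 (19 adjusted over the list alone), with an adjusted p of 0.662 and 0.64 with an estimated correlation. Of 68 cytochrome P450 genes, 1 fell in N2 (0 adjusted over the list alone), and 15 fell and 2 rose in mir-83 (15 adjusted over the list alone), with an adjusted p of 0.666 and 0.709 with an estimated correlation. With plain library sizes, chosen after seeing the data, 25 neuropeptide, 10 glutathione S-transferase, 8 UDP-glycosyltransferase and 8 P450 genes fell in mir-83, 9, 2, 3 and 8 rose, and in N2 3, 2, 4 and 0 fell. Camera still called the lists in both strains, though it hardly responds to a shift of all genes. The P450 list was not called in N2 without N2 day 4 replicate 1 (median -0.10), nor in mir-83 without mir-83 day 12 replicate 1 (median -0.41).

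The 12 genes of the mitochondrial genome counted in the replicate 1 sheet took 1.388% of reads in N2 day 4 (Wilson 95% interval 1.382% to 1.393%), 0.704% in mir-83 day 4 (0.701% to 0.708%), 0.668% in N2 day 12 (0.666% to 0.671%) and 0.542% in mir-83 day 12 (0.539% to 0.544%). Scaled by the TMM library sizes used in the tests, the shares in the same order were 1.22%, 1.12%, 0.587% and 0.457%. There is 1 library per group here, and the intervals cover counting error only.

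A hypothesis was that the day 4 mutant profile lies opposite to the direction in which N2 changes with age. Correlations across genes of the day 4 genotype effect in 1 replicate with the N2 age effect in the other, which share no library, were -0.128 and -0.285. Both are negative, but the one nearer 0 missed the bound set for the hypothesis, so these data do not settle it.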
